A study of Rattus norvegicus with 9 samples.

How the data were processed

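Messenger RNA was profiled in rat bone marrow mesenchymal stem cells (MSCs), the adherent stromal cells that can form bone, fat and cartilage cells. The cells had been kept for 48 hours in a hydrogel that relaxed mechanical stress at a fast, medium or slow rate. There were 9 samples, 3 in each group, and the group of each sample was taken from its labels. Per the labels' protocols, polyadenylated RNA was made into libraries with a QIAGEN kit made for single cells and sequenced on an Illumina instrument. Nothing in the labels says that the 3 samples of a group came from separate animals or separate cultures, so p-values measure the spread between these samples, which may be technical.

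A single deposited table held the values of all samples. Per the file headers, the authors gave a read count per gene and sample, and the values were whole numbers of at least 0 with totals that differed between samples. The authors also deposited an FPKM value per gene and sample. Among genes with 20 or more counts, where this was checked, each FPKM value equalled the count divided by the deposited gene length and by a constant of the sample. That constant lay between 0.9757 and 1.045 times the sample's total count. The table further held, per the file headers, the authors' log2 fold change, p-value and adjusted p-value for each pair of groups, with the test not given in the sources used here. The submitters' processing notes name Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq, without saying which step each was used for, and the mouse build mm10. The gene identifiers in the table are rat Ensembl identifiers, so the build of the coordinates is taken as not given in the sources used here. Coordinates below are those of the deposited table. No source says whether reads were counted by strand, and reads of overlapping or near-identical genes could have been assigned to either.

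The table listed 33539 genes, of which 32545 had a rat Ensembl identifier and 994 were loci without a symbol. Of all genes, 22293 were listed as protein-coding and 11069 had a count of 0 in all 9 libraries. Genes with low counts were removed with the filterByExpr function of edgeR (minimum count 10, smallest group 3), which left 14406 genes holding 99.91% of all counts. Counts were scaled with TMM factors, which ranged from 1.036 to 1.037 in Fast, from 0.9874 to 0.9879 in Medium and from 0.9715 to 0.9812 in Slow. Levels are given as CPM computed with these factors. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with all 9 samples in 1 model with a term for each group. P-values were adjusted over the tested genes by the Benjamini-Hochberg method, and genes under 0.05 were called changed. Besides the 3 pairs of groups, Medium was tested against the midpoint of Fast and Slow, and all 3 groups were tested together. The common biological coefficient of variation was 7.44%.

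A total of 30 gene lists were fixed before the data were examined, as were the samples, the tests, the rule for named genes and all alternatives not said to be added later. Of the 639 entries of these lists, 624 were found in the table. The lists were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists with at least 5 measured members. Named genes followed a rule. In each pair of groups, candidates had an adjusted p under 0.05, a mean of at least 50 counts, a symbol that was not a placeholder or mitochondrially encoded, and no overlap between the libraries of the groups. Of these, the 12 largest rises and 12 largest falls were named for Fast against Slow, and the 8 and 8 largest for the other pairs. For Medium against the midpoint the 5 largest above and the 5 largest below were named without the condition on overlap. Up to 4 members of each list with the smallest adjusted p were added. Some genes that the rule names are not reported here. Any other gene named was chosen after its values were seen, and is said to be.

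The alternatives were other scalings (median-of-ratios factors, upper quartile factors, library size only), DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 samples, limma on log2(FPKM + 1), a replicate block, a 2-fold minimum, protein-coding genes only, only the 6 samples of a pair of groups, and each replicate left out in turn. For the lists, camera with an estimated correlation and fry were run as well. The tests were first run on simulated counts drawn for the 14406 genes. For Fast against Slow, 58% of genes changed 1.5-fold, 90% of those changed 2-fold and 88% of those changed 4-fold were recovered, and 48% of those given a smaller change than these. Of 151 calls 9 were false, and 0 of 50 unchanged lists was called. Genes were drawn independently and 200 were changed, so the simulated lists held no correlation between genes. These rates do not carry over to lists of correlated genes or to data in which many more genes differ. With no gene changed between Medium and Slow, 2 genes were called.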

Results

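The 9 libraries held between 14128980 and 15779328 counts. The totals were 14824154, 15429909 and 14264960 in Fast, 14860845, 14930493 and 14128980 in Medium and 14449520, 15779328 and 14700526 in Slow. Replicate libraries of a group differed by more than counting noise, with a chi-square per degree of freedom between 2.88 and 6.36 over the 9 pairs. All 9 libraries were kept as separate samples, as labelled. Mitochondrially encoded genes took 3.782% of counts in Fast replicate 1 (95% Wilson interval 3.773 to 3.792), against 3.295% (3.286 to 3.304) and 3.213% (3.204 to 3.222) in the other Fast libraries. Slow replicate 3 held 965 genes that were counted in no other library, against 126 to 205 in each of the others. The intervals cover counting error only. Shares of mitochondrial and ribosomal protein genes, the share of the 10 most counted genes and the number of genes with at least 10 counts were compared between the groups in 12 two-sided exact permutation tests. In 7 of these the groups did not overlap and p was 0.1, the smallest that 3 against 3 can give, so none of these permutation tests could pass 0.05. The 10 most counted genes held 13.739 ± 0.189% of counts in Fast, 15.427 ± 0.0382% in Medium and 14.674 ± 0.0528% in Slow (SD, n = 3). Genes with at least 10 counts numbered 14186 ± 80.8, 13975 ± 53.1 and 13958 ± 61.8. Ribosomal protein genes held 2.68 ± 0.0698%, 2.6817 ± 0.0274% and 2.5435 ± 0.047%, and mitochondrially encoded genes 3.4302 ± 0.308%, 3.6017 ± 0.0251% and 3.6266 ± 0.074%.

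The most abundant transcripts named here encode matrix proteins. Fibronectin (Fn1) stood at 37800 ± 914 CPM in Fast, 52900 ± 235 in Medium and 51800 ± 351 in Slow (SD, n = 3). The 3 groups separated in a principal component analysis of log2 CPM. The first component held 47.8% of the variance and set Fast apart from Medium and Slow, and the second held 10.1%.

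**Figure D1:**
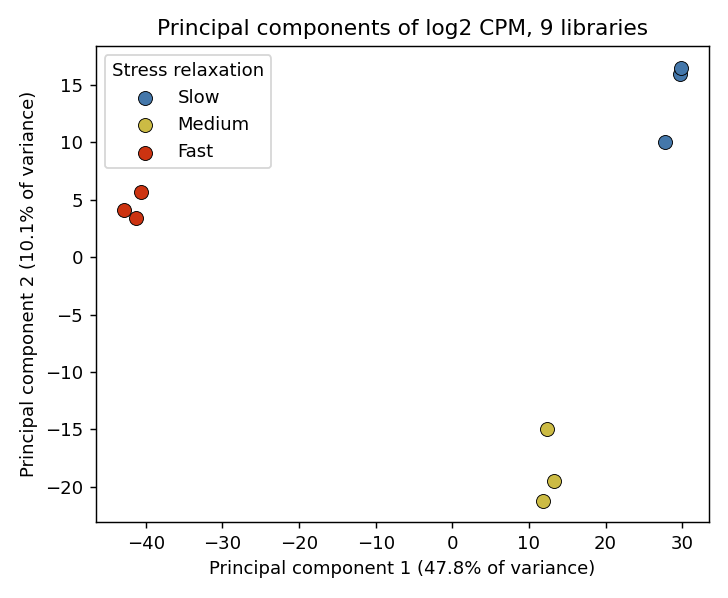
Principal components of log2 CPM in the 9 libraries, with the first component (47.8% of variance) on the x axis and the second (10.1%) on the y axis, in arbitrary units. Each point is 1 library, coloured by group, and the 3 libraries of each group lie together.

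The first comparison, Fast against Slow, set the ends of the range of stress relaxation rates side by side. Ibsp, which encodes bone sialoprotein, was higher in Fast gels, at 348 ± 26.9 CPM in Fast and 50.1 ± 1.16 in Slow (SD, n = 3), a log2 difference of 2.80 ± 0.054 (SE). The phosphatase gene Alpl rose by 1.63 ± 0.034, to 285 ± 3.45 CPM in Fast, and Col1a1 from 9310 ± 54 to 16400 ± 936 CPM. In the opposite direction, the prostaglandin synthase gene Ptgs2 fell by 2.71 ± 0.035 on the log2 scale, from 3230 ± 56.7 to 494 ± 29.6 CPM. Inhba, which encodes the subunit of activin A, fell by 2.67 ± 0.033, from 1220 ± 19 to 192 ± 8.45 CPM.

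The largest rises in Fast over Slow included C6, a terminal complement component, at 17.9 ± 0.748 against 0.633 ± 0.183 CPM (log2 4.79 ± 0.19, edgeR adjusted p = 5.13e-11). The table places C6 (ENSRNOG00000024115) on chromosome 2 from 54466280 to 54533797. Siglec1, a sialic acid receptor of macrophages, rose by 4.43 ± 0.23. The gene of the matrix glycoprotein Sned1 rose by 3.95 ± 0.093, to 145 ± 4.24 CPM, and the aldo-keto reductase gene Akr1c14 by 3.86 ± 0.096. Plagl1, an imprinted zinc finger gene, rose from 3.75 ± 0.381 to 41.4 ± 2.1 CPM. Clec4a1, Plac8, Fat3, Prss16, Spon1 and Clec4a3 rose by between 2.92 and 3.80. Fam50a was also listed among them, but its level in Fast was 13.4 ± 10.3 CPM and limma-voom gave an adjusted p of 0.125, so its value is uncertain. The largest falls were Bpifa2 (-3.97 ± 0.15) and the cytokine gene Tslp (-3.70 ± 0.18). Ccl6 (ENSRNOG00000030021), a chemokine gene on chromosome 10 from 70797124 to 70802782, fell by 2.93 ± 0.054, and Cd93 fell by 2.91 ± 0.071. Il11, Itga7, Lmcd1, Anxa8, Rn60_10_0705.2 and Dcx had log2 differences between -2.83 and -2.60. All of these had an adjusted p under 0.05 and no overlap between the 3 Fast and the 3 Slow libraries.

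**Figure D2:**
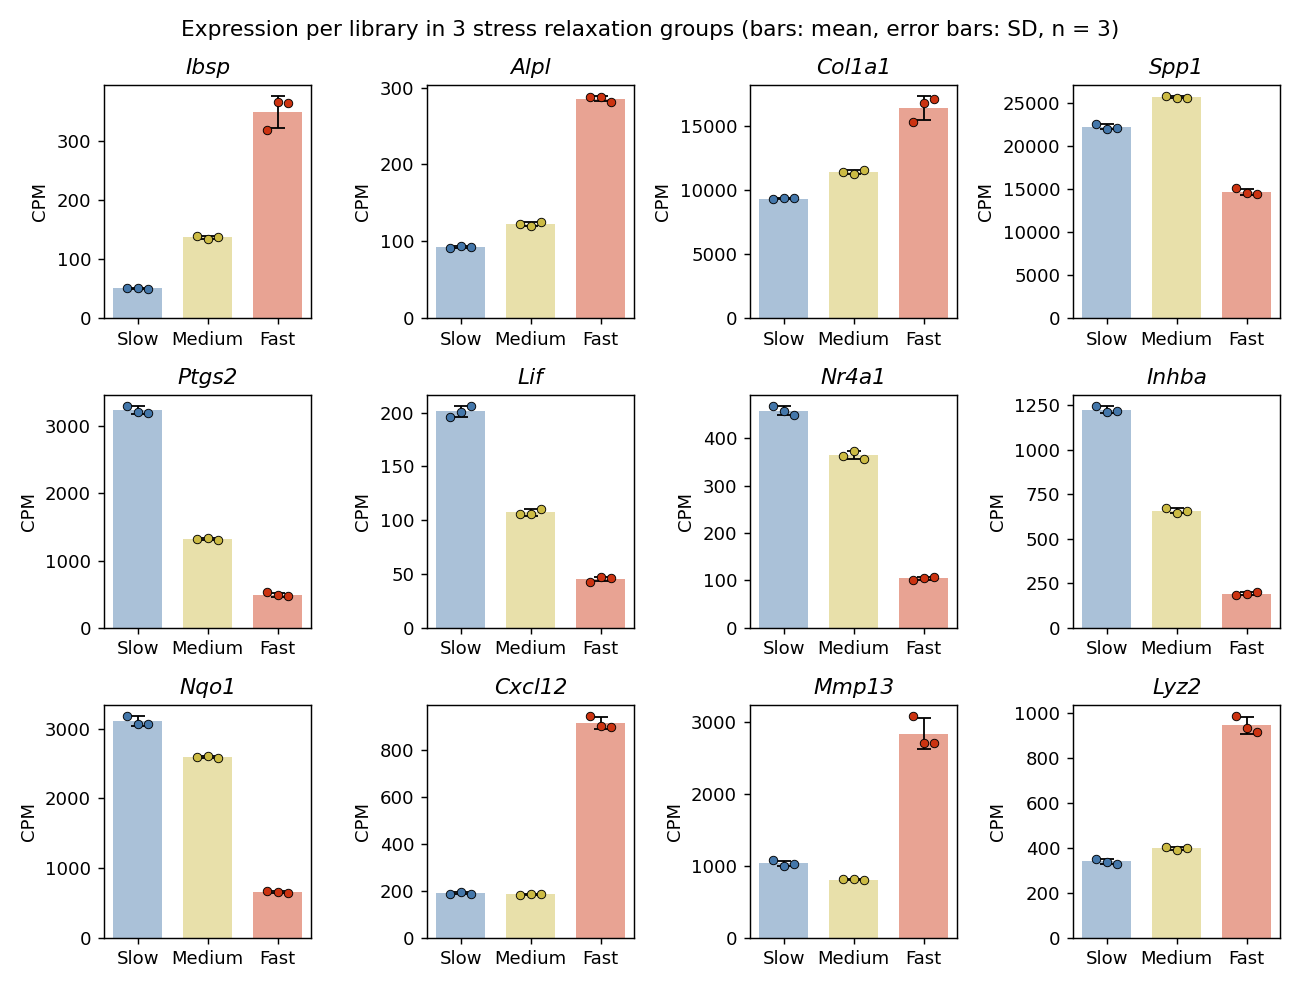
CPM of 12 genes in each library, with linear axes from 0. Bars are group means, error bars the SD and points the 3 libraries of each group. Ibsp rises from 50.1 CPM in Slow to 136 in Medium and 348 in Fast, while Ptgs2 falls from 3230 to 1320 and 494.

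Among the 18 measured osteogenic genes, 11 rose and 4 fell in Fast over Slow, with a median log2 difference of 0.41 (camera adjusted p = 1.49e-05). Spp1, which encodes osteopontin, went against Ibsp, Alpl and Col1a1 at -0.60 ± 0.016, from 22300 ± 299 to 14700 ± 348 CPM. The transcription factor genes of osteoblast commitment, Runx2 and Sp7, were named after their values were seen. They differed by 0.11 ± 0.051 (adjusted p = 0.102) and 0.13 ± 0.063 (adjusted p = 0.126). Of 28 collagens and matrix glycoproteins 18 rose and 7 fell (median 0.27, adjusted p = 3.43e-05). Periostin (Postn) rose by 1.10 ± 0.024 and the lysyl oxidase gene Loxl1 by 1.61 ± 0.048, while Fn1 fell by 0.46 ± 0.014 and Thbs1 by 1.04 ± 0.037. Of 24 matrix proteases and inhibitors 11 rose and 12 fell. The collagenase gene Mmp13 went from 1030 ± 38.9 to 2840 ± 219 CPM, while Plaur and Mmp9 fell by 1.13 ± 0.033 and 0.91 ± 0.027. This list was called lower (adjusted p = 0.00263) with a median of -0.08, and the call was lost with an adjusted p of 0.145 with an estimated correlation. Its median was 0.01 when counts were scaled by library size only.

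Genes that respond within minutes to growth factors and other stimuli were the list with the smallest p. Of 24 immediate early genes 22 fell in Fast and 0 rose (median -1.18, camera adjusted p = 3.1e-43, and 0.000778 with an estimated correlation). Nr4a1 fell from 459 ± 10 to 104 ± 2.7 CPM and Ier3 from 529 ± 16.8 to 121 ± 3.61. The phosphatase genes Dusp6 and Dusp5, which act on MAP kinases, fell by 1.41 ± 0.041 and 1.85 ± 0.055. Antioxidant and NRF2 targets also fell, 16 of 20 with 3 that rose (median -0.38, adjusted p = 2.67e-12). The quinone reductase gene Nqo1 went from 3100 ± 71.4 to 653 ± 11 CPM, Txnrd1 fell by 1.39 ± 0.028, and Gpx3 rose by 1.37 ± 0.036. Of 29 glycolysis and hypoxia genes 21 fell and 2 rose (median -0.32, adjusted p = 1.9e-06), among them the glucose transporter gene Slc2a1 (-0.89 ± 0.029) and Pfkp (-0.85 ± 0.041). Of 14 heat shock genes 6 fell, including Hspb8 (-1.33 ± 0.067), and 0 rose (median -0.11, adjusted p = 0.0189). The heat shock call had an adjusted p of 0.0721 with an estimated correlation, although the estimate of -0.0475 lay below the preset of 0.01.

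Adhesion genes were lower in Fast as well. Of 22 integrins and focal adhesion genes 15 fell and 3 rose (median -0.37, adjusted p = 1.44e-07). Itga7 and Itga8 fell by 2.80 ± 0.067 and 2.25 ± 0.065, while the collagen receptor gene Itga11 rose by 0.87 ± 0.035. Of 19 YAP/TAZ targets, genes that follow mechanical input to the nucleus, 14 fell and 2 rose (median -0.34, adjusted p = 9.2e-08). Ctgf fell by 0.39 ± 0.020 and Igfbp3 by 0.61 ± 0.033. Of 20 TGF-beta and BMP targets 9 fell and 6 rose (median -0.13, adjusted p = 5.15e-06), with Inhba lower and Ltbp2 higher by 0.74 ± 0.024.

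Proliferation genes were higher in Fast. Of 29 cell cycle genes 24 rose and 0 fell (median 0.51, adjusted p = 0.000801), with Mki67 at 64.3 ± 2.63 CPM in Fast and 39.3 ± 1.35 in Slow, and Tpx2, Cdk1 and Top2a higher by 0.54 ± 0.072, 0.52 ± 0.070 and 0.51 ± 0.069. Of 16 interferon response genes 14 rose and 0 fell (median 0.69, adjusted p = 0.00162). Ifit2 rose by 1.65 ± 0.14 and Gbp2 by 1.47 ± 0.13. Of 22 inflammatory and NF-kB targets 11 fell and 5 rose (median -0.03, adjusted p = 4.86e-11). Ptgs2, Il11 and Lif fell by over 2 on the log2 scale and Cxcl3 by 1.14 ± 0.037. The median of this list was 0.03 with upper quartile factors and 0.06 with library size only. Markers of macrophages and other myeloid cells moved in the same libraries: 14 of 19 rose and 3 fell (median 0.69, adjusted p = 3.17e-11). Lyz2 went from 340 ± 11.3 to 947 ± 37.6 CPM and Adgre1 from 292 ± 1.66 to 615 ± 19.6, and Aif1 and Cybb rose by 1.64 ± 0.080 and 0.83 ± 0.044. Myeloid transcripts were thus counted in Slow as well as in Fast. The values do not separate cell types, so whether a difference named here arose in stromal or myeloid cells was not tested.

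Other lists held single genes with large differences without being called as lists. The chemokine gene Cxcl12, counted among both stromal markers and secreted growth factors, rose from 191 ± 3.67 to 918 ± 26.8 CPM. The stromal marker gene Nt5e fell by 1.65 ± 0.039 and Pdgfra rose by 0.93 ± 0.030. Of 16 mesenchymal stromal markers 4 rose and 10 fell (camera adjusted p = 0.876), and of 24 secreted growth factors 8 rose and 13 fell (0.2), with Pdgfa lower by log2 -1.68 ± 0.052. Of 12 chondrogenic genes 2 rose and 3 fell (0.0709), with the cartilage genes Acan and Sox9 at -1.43 ± 0.036 and -0.99 ± 0.057. Of 16 adipogenic genes 10 rose and 3 fell (0.316), including Apoe (1.47 ± 0.054) and the lipid droplet gene Plin2 (-1.38 ± 0.031). Of 21 WNT pathway genes 12 rose and 5 fell (0.136), with Sfrp1 at 1.97 ± 0.055, Wnt5a at -1.05 ± 0.035 and Axin2 at -1.29 ± 0.073.

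The remaining lists were not called either. They were contractile and SRF targets (9 rose and 8 fell of 20, adjusted p = 0.58), oxidative phosphorylation (0 and 4 of 30, 0.634), and cholesterol synthesis and uptake (10 and 6 of 23, 0.58). The unfolded protein and integrated stress response (6 and 11 of 23, 0.138), p53 targets and apoptosis (5 and 8 of 19, 0.0963), mechanosensitive channels and primary cilium (4 and 3 of 17, 0.381) and autophagy and lysosome (7 and 6 of 22, 0.609) were also not past 0.05. Among cell type markers, those of lymphocytes and neutrophils (4 and 0 of 5, 0.0709), endothelium (1 and 3 of 8, 0.381) and osteoclasts (3 and 2 of 8, 0.25) did not pass, and the erythroid list had 3 measured genes, of which 1 fell, and was not tested. For chondrogenic genes, cholesterol genes, autophagy genes and osteoclast markers the median, the mean and the direction of the test did not all have the same sign. Adjusted over the list alone, 1 more gene rose in each of YAP/TAZ targets, proteases, inflammatory targets, NRF2 targets and osteoclast markers, 2 more rose among glycolysis genes, and 1 more fell in each of growth factors, TGF-beta and BMP targets and autophagy genes, while the other counts were equal.

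In all, 6177 of 14406 genes (42.9%) differed between Fast and Slow at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3049 higher and 3128 lower in Fast, and 14 of 29 lists were called, 5 higher and 9 lower. Of these genes 1148 differed at least 2-fold, 682 higher and 466 lower. The split depended on scaling: 3693 higher and 2494 lower with upper quartile factors (59.7% higher against 49.4%), and 4132 and 2216 (65.1%) with library size only. Genes with lower levels tended to be higher in Fast (Spearman rho of log2 difference and mean log2 CPM -0.218 over 14406 genes). How far this bears on the genes that differed at least 2-fold was not tested. The authors' deposited table gave 4855 genes with an adjusted p under 0.05 for these groups, of which 4788 were called here in the same direction. Both results rest on the same samples, so the shared direction is no independent support, here or in the pairs below.

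The next comparison, Medium against Slow, covered the slower part of the range. Inflammatory transcripts were lower in Medium. Ptgs2 fell by 1.29 ± 0.033, from 3230 ± 56.7 to 1320 ± 10.6 CPM, and Il6 by 1.15 ± 0.061, from 160 ± 5.98 to 71.7 ± 2.36 CPM (SD, n = 3). The chemokine genes Ccl6 and Ccl20 fell by 1.64 ± 0.049 and 1.24 ± 0.065. Ibsp was higher in Medium, at 136 ± 2.26 against 50.1 ± 1.16 CPM (log2 1.45 ± 0.055), and so was Frzb, which encodes a secreted WNT antagonist, at 11.7 ± 0.316 against 2.77 ± 0.783 CPM (2.08 ± 0.17).

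Other genes with the largest rises in Medium over Slow were Matn2 (1.84 ± 0.15), Capn6 (1.53 ± 0.16), Lppr3 (1.47 ± 0.24), Prss16 (1.45 ± 0.24) and Siglec1 (2.02 ± 0.26). The call for Siglec1 was lost with limma on log2(FPKM + 1), where its difference was 0.5 (adjusted p = 0.0624). Tslp fell by 1.51 ± 0.15, Rn60_10_0705.2 by 1.58 ± 0.13 and Igsf9b by 1.21 ± 0.14. Ebna1bp2, Hnrnpc and Mast4 were among the largest differences with levels that varied within groups, as for Hnrnpc at 22.3 ± 13.1 CPM in Slow, and their values are uncertain. The call for Hnrnpc was lost without Medium replicate 1, 2 or 3 (adjusted p = 0.0501, 0.06 and 0.0692) and without Slow replicate 1 or 3 (0.0556 and 0.0886), and with limma-voom or limma on log2(FPKM + 1) (0.12 in each). That for Ebna1bp2 was lost with the same methods (0.125 and 0.0522).

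Of the 22 inflammatory and NF-kB targets 17 fell and 1 rose in Medium (median -0.42, camera adjusted p = 1.06e-72, and 0.000106 with an estimated correlation). Of 18 osteogenic genes 10 rose and 1, Bmp2 (-0.86 ± 0.079), fell (median 0.31, adjusted p = 4.24e-13), with Alpl higher by 0.40 ± 0.035 and Spp1 by 0.21 ± 0.016. Genes of protein folding in the endoplasmic reticulum were lower: 12 of 23 in the unfolded protein and integrated stress response list fell and 1 rose (median -0.21, adjusted p = 1.06e-12), including Hspa5 (-0.49 ± 0.031) and Hsp90b1 (-0.34 ± 0.023). Of 24 matrix proteases and inhibitors 11 fell and 2 rose (median -0.13, adjusted p = 3.44e-12), with Mmp3 from 970 ± 17.6 to 508 ± 9.98 CPM and Timp3, an inhibitor gene, higher by 0.96 ± 0.084. Of 28 collagens and matrix glycoproteins 14 rose and 6 fell (median 0.13, adjusted p = 1.99e-05), with Col6a3 at 0.62 ± 0.022 and Col8a1 at -0.59 ± 0.041. Of 19 myeloid markers 9 rose and 1 fell (median 0.25, adjusted p = 1.46e-08), with Adgre1 at 0.48 ± 0.031 and Aif1 at 0.80 ± 0.084.

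Further lists were called in Medium. Glycolysis and hypoxia genes fell (15 of 29, 0 rose, median -0.13, adjusted p = 1.42e-10), and so did integrins and focal adhesion genes (9 of 22, 1 rose, -0.09, 3.06e-08). NRF2 targets (10 of 20 fell, 1 rose, -0.15, 3.5e-08), secreted growth factors (9 of 24 fell, 0 rose, -0.15, 2.29e-07) and immediate early genes (7 of 24 fell, 2 rose, -0.07, 2.46e-06) were lower. So were p53 targets and apoptosis genes (7 of 19 fell, 1 rose, -0.14, 8.59e-05), stromal markers (6 of 16 fell, 1 rose, -0.11, 0.000455) and YAP/TAZ targets (5 of 19 fell, 2 rose, -0.04, 0.0027). Cell cycle genes (2 of 29 rose, 0.21, 0.00151), chondrogenic genes (4 of 12 rose, 0.21, 0.00566) and interferon response genes (5 of 16 rose, 0.29, 0.00566) were higher, with 0 that fell in each. The 2 cell cycle genes, Mki67 and Foxm1, were no longer past 0.05 without Slow replicate 2 (edgeR adjusted p = 0.0634 and 0.127). Sox9 and Acan, lower in Fast than in Slow, were higher in Medium than in Slow by 0.34 ± 0.054 and 0.19 ± 0.034. Adjusted over the list alone, the counts were higher for many of these lists, for example 22 falling glycolysis genes and 20 falling inflammatory targets.

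In total, 1485 genes (10.3%) differed between Medium and Slow, 683 higher and 802 lower, and 101 of them at least 2-fold, 58 higher and 43 lower. The split turned with the scaling, to 758 higher and 707 lower with upper quartile factors (51.7% higher against 46%) and 800 higher and 693 lower with library size only (53.6%). Of 29 lists 17 were called, 6 higher and 11 lower. The authors' deposited table gave 1804 genes with an adjusted p under 0.05, of which 1401 were called here in the same direction.

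**Figure D3:**
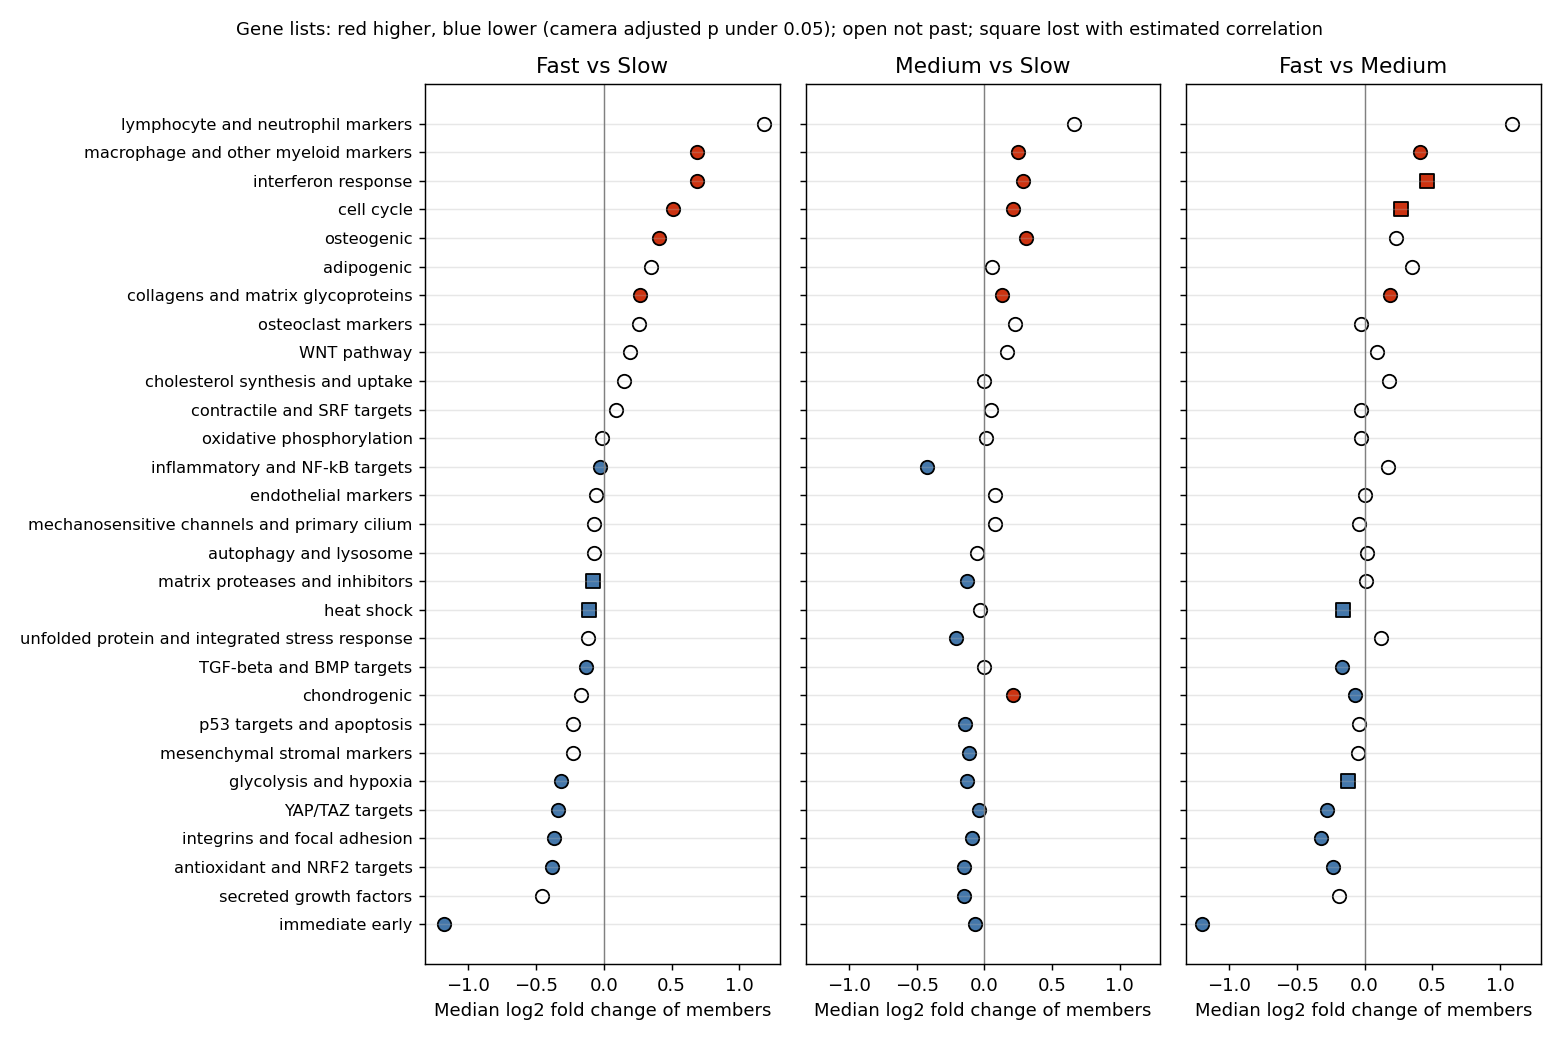
Median log2 fold change of the members of 29 gene lists (x axis) in the 3 pairs of groups, ordered by Fast against Slow. Red and blue mark lists called higher and lower with camera, open circles lists not called and squares calls lost with an estimated correlation. Immediate early genes lie at -1.18 in Fast against Slow, -0.07 in Medium against Slow and -1.20 in Fast against Medium.

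The last pair, Fast against Medium, covered the faster part of the range. Immediate early genes were lower in Fast, with Nr4a1 at 104 ± 2.7 against 364 ± 8.48 CPM and Ier3 at 121 ± 3.61 against 299 ± 7.9 (SD, n = 3). Nqo1 fell from 2590 ± 9.82 to 653 ± 11 CPM. Cxcl12 rose from 185 ± 2.62 to 918 ± 26.8 CPM and Mmp13 from 810 ± 2.01 to 2840 ± 219. Alpl and Ibsp rose by 1.22 ± 0.033 and 1.35 ± 0.049, while Spp1 fell by 0.81 ± 0.016, from 25700 ± 109 to 14700 ± 348 CPM. As a list, osteogenic genes were not called in Fast against Medium. Of 18 measured, 7 rose and 5 fell (median 0.23, camera adjusted p = 0.0803).

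The largest rises in Fast over Medium were in C6 (3.81 ± 0.18), Akr1c14 (2.70 ± 0.086), Sned1 (2.62 ± 0.082), Chi3l1 (2.60 ± 0.22), Plagl1 (2.53 ± 0.10), Plac8 (2.43 ± 0.23) and Ptn (2.43 ± 0.20), besides the uncertain Fam50a. The largest falls were in Anxa8 (-3.46 ± 0.24), Bpifa2 (-3.46 ± 0.16) and Klhl40 (-3.30 ± 0.12), followed by Xcl1, Dcx, Lmcd1, Wipf3 and Iqcd at between -3.07 and -2.25. Klhl40 (ENSRNOG00000019390) lies on chromosome 8 from 130416355 to 130421871 in the table.

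Of 24 immediate early genes 23 fell and 0 rose in Fast against Medium (median -1.20, camera adjusted p = 7.89e-49, and 0.000526 with an estimated correlation). Egr1 was among them (-1.15 ± 0.036). NRF2 targets (12 of 20 fell, 4 rose, -0.23, 5.06e-09), YAP/TAZ targets (11 of 19 fell, 1 rose, -0.28, 6.24e-07), TGF-beta and BMP targets (11 of 20 fell, 5 rose, -0.17, 1.32e-06) and integrins and focal adhesion genes (11 of 22 fell, 2 rose, -0.32, 0.000241) were lower. Chondrogenic genes were called lower with 4 of 12 that fell and 2 that rose (-0.07, 0.000418), among them Acan (-1.62 ± 0.036) and Sox9 (-1.33 ± 0.057). Myeloid markers were higher (13 of 19 rose, 1 fell, 0.41, 1.28e-07), with Lyz2 at 947 ± 37.6 against 398 ± 6.44 CPM, and so were collagens and matrix glycoproteins (17 of 28 rose, 5 fell, 0.19, 0.00493). A further 4 calls were lost with an estimated correlation. Cell cycle genes rose (14 of 29, 0 fell, 0.27, 0.0158), with an adjusted p of 0.0792 with an estimated correlation and of 0.0522 without Fast replicate 1. Interferon response genes rose (7 of 16, 0 fell, 0.46, 0.016), with an adjusted p of 0.078 with an estimated correlation. Glycolysis and hypoxia genes (13 of 29 fell, 4 rose, -0.12, 0.0125) and heat shock genes (7 of 14 fell, 0 rose, -0.16, 0.0133) had adjusted p-values of 0.179 and 0.0759 with an estimated correlation. The estimates were 0.00744 for cell cycle, -0.0147 for interferon, 0.0506 for glycolysis and -0.0485 for heat shock genes. Only that for glycolysis lay above the preset of 0.01, so a larger correlation does not account for the other losses. Adjusted over the list alone, for example, 13 integrin and focal adhesion genes, 13 NRF2 targets and 12 TGF-beta and BMP targets fell, and 15 cell cycle, 8 interferon and 14 myeloid genes rose.

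Between Fast and Medium 4750 genes (33%) differed, 2254 higher and 2496 lower in Fast, and 729 of them at least 2-fold, 386 higher and 343 lower. Of 29 lists 12 were called, 4 higher and 8 lower. Some lists that were lower in Medium than in Slow were not called lower in Fast than in Medium. Of 22 inflammatory and NF-kB targets 13 rose and 7 fell in Fast against Medium (median 0.17, camera adjusted p = 0.902), and of 23 genes of the unfolded protein and integrated stress response 11 rose and 3 fell (0.12, 0.175). With upper quartile factors 2734 genes were higher and 1990 lower (57.9% higher against 47.5%), and with library size only 3151 and 1781 (63.9%). The authors' deposited table gave 3687 genes with an adjusted p under 0.05, of which 3638 were called here in the same direction.

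The position of Medium within the series was then examined. The muscle gene Klhl40 and the annexin gene Anxa8 were highest in Medium, at 30.2 ± 2.43 and 12 ± 1.45 CPM, each 2.1 above the midpoint of Fast and Slow on the log2 scale (SE 0.091 and 0.17). The chemokine gene Ccl20 was lowest in Medium, at 37.4 ± 3.2 CPM against 107 ± 4.64 in Fast and 88.1 ± 5.33 in Slow (-1.38 ± 0.058 from the midpoint). C6 and Rrad lay below the midpoint by log2 -1.41 ± 0.19 and -1.37 ± 0.13. Nhp2, Ebna1bp2, Rps6, Mast4 and Hnrnpc were also among the largest deviations, and all 5 are uncertain, because their levels varied within groups. The call for Mast4, for example, was lost without Medium replicate 3 (adjusted p = 0.058).

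In edgeR's quasi-likelihood test 1741 genes differed from the midpoint, 1037 above and 704 below, and 111 of them by at least 1 on the log2 scale. With library size only the split was 859 above and 964 below (47.1% above against 59.6%). Among 6086 genes that differed over the 3 groups, the mean of Medium lay between Fast and Slow in 4263 (70%), above both in 972 (16%) and below both in 851 (14%). For the 1148 genes that differed at least 2-fold between Fast and Slow, the median position of Medium was 0.282 of the way from Slow to Fast on the log2 scale (quartiles 0.109 and 0.444).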

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

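Both tests in this part were chosen after the counts they concern had been seen. In Slow replicate 3, 965 genes had counts while having none in the other 8 libraries, against 126 to 205 such genes in each other library, a signal outside the genes compared between groups. Those 965 genes held 1593 counts, or 0.0108% of the library's total (95% Wilson interval 0.0103 to 0.0114), and the highest had 16. RNA of another tissue may be the source and cannot be excluded: the 10 highest held 4.83% of the signal (3.88 to 6), but the profile of such a tissue was not measured, so no low share decides. Genomic DNA in the library may also be the source and cannot be told apart from it: olfactory receptor genes, which few tissues transcribe, had 63 counts over 960.3 kilobases against 1047 over 5233 kilobases in other silent protein-coding genes, a ratio of rates of 0.328 (0.25 to 0.423) that spans the bound of 0.33. No biological explanation was tested, since the other Slow libraries did not show the signal.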

How the results depend on the processing

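The alternative without both Fast replicate 1 and Slow replicate 3 was chosen after seeing the data. No named gene reversed under any alternative run. Of 2767 values of named genes under alternatives in Fast against Slow, 23 (7 genes) were no longer past 0.05, as were 135 of 2285 (22 genes) in Medium against Slow, 24 of 2601 (4 genes) in Fast against Medium and 31 of 199 (5 genes) for the midpoint. Counts of changed genes stayed within 1.5 times of those reported except with the 2-fold minimum, which by its construction left 1148, 101 and 729 genes in the pairs of groups, 111 for the midpoint and 1209 over the 3 groups. With an estimated correlation 12, 17 and 8 of the 14, 17 and 12 called lists were still called. Their camera adjusted p-values were larger than with the preset, the smallest being 0.000106 (inflammatory targets in Medium against Slow). This held even where the estimate lay below the preset, as for osteogenic genes in Fast against Slow (estimate -0.0281). There camera gave an adjusted p of 0.00946 against 1.49e-05, so the setting changes more than the correlation. For the lists, fry, which does not compare a list with other genes, called 27 lists for Fast against Slow and 24 for Fast against Medium. DESeq2 called 5313, 1252 and 3984 genes in the pairs, 1528 for the midpoint and 5257 over the 3 groups. With each replicate left out in turn the counts were 5414 to 6067 (Fast against Slow), 1011 to 1905 (Medium against Slow), 3920 to 4656 (Fast against Medium), 1208 to 2003 (midpoint) and 5287 to 5932 (3 groups). Called lists numbered 14 to 16, 17 to 19 and 12 in each fit. Without both Fast replicate 1 and Slow replicate 3 the counts of genes were 5449, 1482, 4537, 1820 and 5435, and of lists 15, 18 and 12. With library size only, 6 genes called in Fast against Slow and 2 called in Fast against Medium had the opposite sign, and the median of all genes moved by 0.0859 and 0.07. In Fast against Medium 1 called gene turned without Fast replicate 2 and 1 without Medium replicate 3. For the midpoint 1 turned with limma on log2(FPKM + 1). With a replicate block the counts were 6111, 1397, 4643, 1699 and 5966 genes and 14, 18 and 12 lists. The replicate numbers share nothing else in the labels: deviations from group means correlated at -0.032 to 0.046 for the same number and -0.065 to 0.048 for different numbers, and 5 of 9 samples correlated best with their own number. The call of Cd2 in Fast against Medium (adjusted p = 0.0378) was lost without any single Fast or Medium replicate (0.0509 to 0.137) and with DESeq2 (0.0894). In all 9 libraries 11069 genes had no count, and whether more depth would count them was not tested.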

Other observations

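In this part the list tests for ERK output and imprinted genes and the counts over other splits of the samples were written before their results were seen, and the tests of cell shares, scaling and harvest labels were chosen after.

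Feedback regulators and targets of ERK signalling outside the fixed lists were lower in Fast than in Slow. Of 13 such genes 8 fell, 1 rose and 4 did not pass (median -0.34). Phlda1 fell by 2.23 ± 0.044, Spry4 by 1.44 ± 0.049, Epha2 by 1.08 ± 0.065 and Etv4 by 0.99 ± 0.075 on the log2 scale (SE, n = 3 per group), while Spry1 rose by 0.66 ± 0.10. Among 10 measured imprinted genes, Peg3, Grb10 and Ndn rose by 1.27 ± 0.059, 1.00 ± 0.040 and 0.61 ± 0.089, Gnas fell by 0.15 ± 0.039, and 6 did not pass (median 0.44). Itgam, Cd14 and Cd53, members of the myeloid list named after their values were seen, fell in Fast by 0.17 ± 0.033, 0.27 ± 0.032 and 0.38 ± 0.065. They belong to 9 genes that most myeloid cells share, of which 4 rose: Csf1r, Tyrobp, Fcer1g and Spi1, by between 0.66 and 0.79.

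The immediate early genes were lower in Fast than in Slow (median -1.18). The median nearest to 0 over 3 other scalings was -1.09, so the choice among these scalings does not account for the difference. That outcome was nearly fixed in advance, since even library size only moved the median of all genes by just 0.0859. Scaling of another kind was not tested. A hypothesis is that sustained ERK output was lower in Fast gels, consistent with the median of -0.34 in the list of ERK output genes (unadjusted camera p = 6.47e-07, and p = 0.0227 with an estimated correlation), although transcripts do not measure ERK activity. Handling at harvest may also move such short-lived transcripts and cannot be told apart from the groups, because 0 of the 9 samples have labels for a harvest time, order or batch. The rate of stress relaxation itself stays open, as untested.

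The myeloid markers were higher in Fast than in Slow (median 0.69 over 19 genes). A lower share of stromal cells would raise the markers of every other cell type alike. As a check, 20 such markers in no other list were compared by type. They moved apart (permutation test of the Kruskal-Wallis statistic with 10000 permutations of the genes, taken as independent, p = 3e-04). Medians were 0.01 for endothelial, 0.58 for osteoclast, -0.45 for erythroid and 1.18 for lymphocyte and neutrophil markers, most at a few CPM. Only 5 of 18 lymphocyte and neutrophil markers and 3 of 13 erythroid markers passed the filter for low counts. That filter can keep a gene through 1 group alone, which may favour markers high in that group. The test does not decide on a lower stromal share as the whole cause. The list that stood highest holds neutrophil genes such as Camp, and neutrophils are themselves myeloid cells. At 10 CPM or more in Fast were 5 of the 20 markers: Camp (1.15 ± 0.12), Esam (0.44 ± 0.082), Tie1 (0.25 ± 0.12), Acp5 (0.10 ± 0.042) and Egfl7 (-0.13 ± 0.13). Camp and Esam passed an adjusted p of 0.05. Other forms of this test were also run after the values were seen. The Kruskal-Wallis p from the chi-square distribution was 0.00356, and an exact rank sum test of lymphocyte and neutrophil against endothelial markers gave p = 0.00253, or 0.0152 after multiplying by the 6 pairs of lists. The pooled median of the 20 was 0.34 (95% bootstrap interval -0.06 to 0.84), which did not decide. A different set had 0.01 (-0.73 to 0.25). It held all 19 measured endothelial, osteoclast and erythroid markers, including those that are also in other lists. A larger share of myeloid cells as the whole cause would raise all members of the list by about the same fold. That holds only if the kinds of myeloid cells present were the same in both groups, which was not tested. Single values, known when chosen, did not show such an equal rise. Among the 9 genes that most myeloid cells share 4 rose and 3 fell, from -0.38 ± 0.065 (Cd53) to 0.79 ± 0.045 (Tyrobp). The 10 other members ran from 0.48 ± 0.052 (Cd68) to 2.24 ± 0.32 (C1qb). A bootstrap over genes did not decide: the medians were 0.06 and 1.37, a difference of 1.31 (0.28 to 1.91) whose interval spans the bound of 0.5. A larger share as part of the cause cannot be excluded. A response of the cells to the gel may also raise these markers and stays open.

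Plagl1, which was 41.4 CPM in Fast and 3.75 in Slow, is known to regulate a network of imprinted genes. A hypothesis is that this network rose with it. The list of 14 imprinted genes, written after Plagl1 was seen and before its own values were, had a median of 0.44 over 10 measured genes and was higher in Fast (unadjusted camera p = 0.00612, and p = 0.0287 with an estimated correlation). Among the 10 genes 3 rose and 1 fell. Calls were thus no more frequent than over all tested genes, of which 42.9% were called in Fast against Slow. Igf2 stood at 0.15 ± 0.41 (edgeR adjusted p = 0.795), and the test may reflect few genes.

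Other splits of the samples bore on whether an arbitrary assignment of libraries to groups gives such counts. The 10 splits of 3 against 3 are too few for a share under 0.05, with 1 split, the real one, as large in each case. The real and the highest other counts were 6177 and 2 genes (Fast against Slow), 1485 and 1 (Medium against Slow) and 4750 and 1 (Fast against Medium), and 14 and 9, 17 and 13, and 12 and 4 lists. Every other split mixes the real groups, so a real difference widens the spread within groups and keeps gene counts low. Such counts are no baseline for groups without a difference. Even so, the other splits called a median of 6, 6 and 3 lists. Over the 3 groups, 1 of 100 splits, the real one, gave as many genes as the real 6086, with 4135 in the highest other. That share lies under 0.05 for an arbitrary assignment of these libraries. A chance difference between cultures cannot be excluded by it, because the libraries of a group may be technical repeats. For the midpoint, 2 of 100 splits reached the real 1741, under the bound of 5% set before. That bound was the wrong one, since the highest other split gave 2005 while keeping the 3 Fast libraries together and mixing Medium with Slow, so the position of Medium is left open. The highest other split over the 3 groups also keeps the Fast libraries together, so both counts bear mainly on the difference of Fast from the other groups.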
